A study of Caenorhabditis elegans with 2 samples.

How the data were processed

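ChIP-seq for MBF-1 was carried out by the authors on whole, mixed-sex L2 larvae of C. elegans strain OP427, which carries the unc-119(ed3) mutation and the integrated transgene wgIs427. The chromatin was sheared by sonication, per the labels. The labels name 2 biological replicates with separate biological samples, which form 1 group. Replicate numbers were taken from the labels.

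The authors' deposited lists are in narrowPeak format. Per the labels' accompanying file lists, the candidate regions were called for each replicate and for the pooled replicates from alignments set against a control alignment, and the IDR-thresholded list derives from the pooled list and both replicate lists. The aligner, the peak caller, its settings and the IDR threshold are not given in the sources used here. The signal value of each region is the authors' own, and the scale of the caller is not stated, so it was used to rank and filter regions and to describe them within a list. In the deposited IDR list the q field, a −log10 of a q-value by the definition of the format, ran from 0.712 to 0.841, which is a q of 0.194 to 0.144. In the deposited replicate lists it ran from 0.0178 to 0.921 and from 0.0177 to 2.05. The p field was not used here. Regions had a usual width of 376 bp in replicate 1 and 380 bp in the other ce11 lists. Read depth is unknown here, and alignments and signal tracks were not analysed here. Because candidate lists hold background, a region in them was not read as bound.

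Coordinates are those of the ce11 lists, given from 1. The reference sequence and Ensembl release 115 annotation of WBcel235, the same assembly as ce11, were used for gene starts, features and sequence. Mitochondrial protein-coding genes took RefSeq symbols where gene ends lay within 100 bp. Lists in ce10 coordinates served only for counts and signals, and nothing was converted between assemblies.

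For replicate agreement, each IDR peak took the highest signal among the candidate regions of a replicate that overlapped it by at least 1 bp, and Spearman's rho and Pearson's r were tested with 100000 permutations. Shared top regions were compared with 10000 draws. Gene starts, motifs and G+C were tested with 10000 random placements or draws, so that the smallest 2-sided p is 0.0002. Draws for motifs and G+C came from the 29844 pooled regions outside the IDR peaks, matched on having a gene start within 500 bp. All pooled mitochondrial regions were IDR peaks, so the mitochondrial peaks had no mitochondrial background in these draws. For the G+C match of peaks far from starts, each peak drew 1 of the 100 far regions outside the IDR peaks nearest to it in G+C, with ties broken at random. Gene lists were tested with Fisher's exact test (2-sided) over 46890 nuclear genes, with Benjamini-Hochberg adjustment over 20 lists, and motifs with adjustment over 13. Genes that share a promoter are not independent in this test. An alternative with circular shifts of the summits keeps neighbouring genes together, but it does not keep the share of summits at gene starts. Chromosome counts were tested with an exact binomial test and a Monte Carlo chi-square. Intervals of shares are exact Clopper-Pearson at 95% and cover counting error only. Of the symbols given, 12 of 16 for amino acid stress and 21 of 22 for intestine were found in the annotation.

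The tests, the gene lists, the motifs and the alternatives were fixed before the data were examined, except those said to be added later. The genes and regions named were fixed by rule: mbf-1 and unc-119; the 25 IDR peaks with the highest signal, by the gene with the nearest start within 1000 bp or else by position; up to 4 genes of each list past an adjusted p of 0.05 and up to 2 of every other list; and the 3 peaks with the largest rank disagreement, of which the last was tied. Alternatives were the 66 IDR peaks of highest signal, each replicate alone, other windows, overlaps, backgrounds and gene sets, and the ce10 lists. Nuclear, X, autosome and mitochondrial subsets, the omission of the 2 farthest peaks and overlapping peaks counted once were added after the data were seen.

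The procedures were tested on simulated data. With 12 peaks planted at ribosomal protein genes the list was called in 30 of 30 simulations and with none planted in 0 of 30, over 46890 genes. Another list was called 3 and 2 times. Shares at gene starts were called in 20 of 20 simulations with 55 of 111 peaks planted and in 0 of 20 without. Against a background share of 0.1, a motif at a share of 0.4 in the peaks was called in 20 of 20 simulations, and one at a share of 0.1, as in the background, in 0 of 20. Rank agreement was called in 100 of 100 simulations at a true correlation of 0.6 and in 4 of 100 at 0. The planted effects were larger than several found here, such as 7 ribosomal protein genes at peaks and a rho of 0.209 on the autosomes. Power for smaller effects was not simulated. Simulated peaks that were not planted lay at random positions, without the preference of the real peaks for gene starts. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and BLAST+ 2.17.0.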

Results

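MBF-1, the worm member of the multiprotein bridging factor family of transcriptional coactivators, was profiled by ChIP-seq in whole L2 larvae of Caenorhabditis elegans. The animals came from a transgenic line that expresses MBF-1 with a GFP-FLAG tag at its C-terminus. The design held 1 group of 2 biological replicates and no comparison group. The comparisons were therefore between the replicates, and between the called peaks and other genes, positions or regions of the genome. In the ce11 assembly the candidate lists, which hold background by design, had 19135 regions for replicate 1, 23203 for replicate 2 and 30000 for the pooled replicates. The list that the authors thresholded on the irreproducible discovery rate (IDR), a measure of rank consistency between replicates, held 132 peaks. These were the 132 pooled regions of highest signal, 13 of them with no region in replicate 2 and 2 with none in replicate 1, with signal values of 55.6 to 8355 on the authors' scale and a median of 74.9. Of the 132 peaks, 111 lay on the nuclear chromosomes and 21 on the mitochondrial genome. The read depth behind each list is unknown here, and each signal value is the authors' own for its region.

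The locus of the tagged gene itself carried no region in any of the ce11 lists. mbf-1 (WBGene00003148) lies on chromosome IV at 11479354 to 11480369, on the minus strand. In the pooled list, no candidate region touched the 57696 bp from 11457689 to 11515384 around it. The gap was 59942 bp in replicate 1 and 53755 bp in replicate 2. At unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935), the gene mutated in this strain, no IDR peak was called. Within 1000 bp of unc-119, replicate 2 had 4 candidate regions, the highest at a signal of 16.2, and the pooled list had 3, the highest at 23.5. Replicate 1 had none there.

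The first question was how far the replicates ranked the peaks alike. All 111 nuclear IDR peaks had a candidate region in both replicates, and 6 of the 21 mitochondrial peaks did. Over these 117 peaks Spearman's rho of the replicate signals was 0.581 and Pearson's r was 0.984 (2-sided permutation p = 1e-05 for each, the smallest that 100000 resamples can give). The correlation runs across peaks of 2 libraries, and peaks are not independent replicates. These peaks were selected on pooled signal and on having a region in both replicates, so every permutation p here describes the order within the selected peaks and does not test agreement between the replicates at large. For the 37 X peaks rho was 0.825 (permutation p = 1e-05), and for the 74 autosomal peaks it was 0.209 (permutation p = 0.0735), while Pearson's r was 0.942 and 0.649 (permutation p = 1e-05 for each). Over the 11 settings of this family the Benjamini-Hochberg adjusted permutation p was 1.22e-05 on X and 0.0735 on the autosomes, and the difference between them was not tested. On the nuclear chromosomes alone rho was 0.510 and r was 0.921, and r was 0.862 without the 2 peaks farthest from the median of replicate 1. Among the 66 IDR peaks with the highest signal, 51 had a region in both replicates and rho was 0.891.

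The rank disagreed most at 4 peaks, the last 2 of them tied. A peak at the non-coding RNA gene F08G2.13 (chromosome II, 13834344 to 13834723) had a signal of 17.7 in replicate 1 and 49.4 in replicate 2. An intergenic peak on X at 1909351 to 1909730 had signals of 18.5 and 47.7. The peak at the snoRNA gene C51F7.3 (chromosome V, 12303551 to 12303930) had signals of 20.5 and 51.6. At the non-coding RNA gene Y65B4BR.10 (chromosome I, 536645 to 537024) the order was the other way, with 45.5 in replicate 1 and 20.7 in replicate 2.

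**Figure D1:**
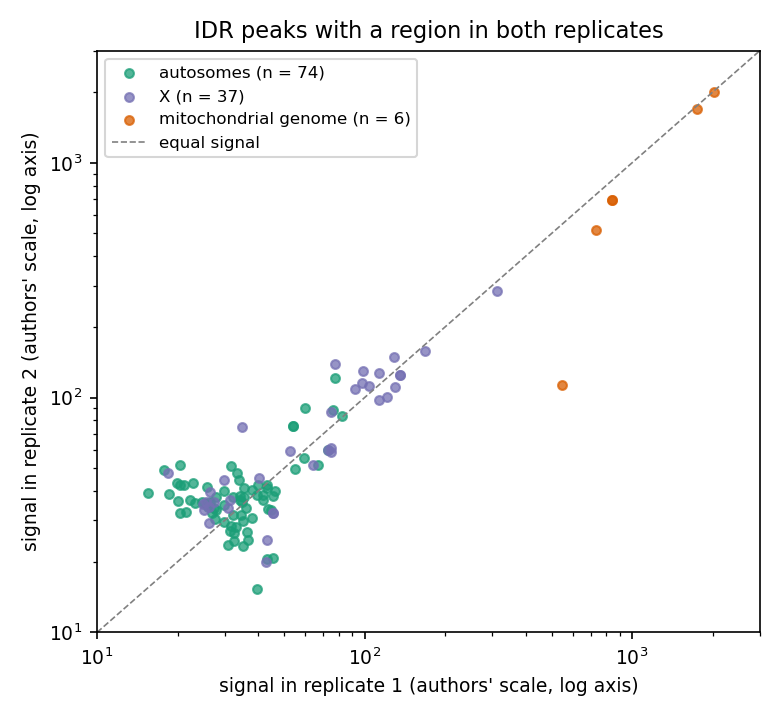
Signal of the overlapping candidate region in replicate 1 (x axis) and replicate 2 (y axis), both on log axes in the authors' units, for the 117 IDR peaks with a region in each; points are peaks and the dashed line marks equal signal. X peaks spread along the line (rho 0.825), while the 74 autosomal peaks form a cloud near the low end (rho 0.209).

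The strongest regions of each replicate were compared without the IDR selection. Of the 132 candidate regions with the highest signal in replicate 1, 47.7% overlapped one of the 132 highest of replicate 2, against 0.538% for regions drawn at random from replicate 2 (n = 132 regions, 1-sided empirical p = 1e-04, the smallest that 10000 draws can give). For the 66 highest regions of each the share was 60.6%, and for the 264 highest it was 34.8%.

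The mitochondrial genome held the highest signals, and many of its peaks had no region in replicate 2. Of the 25 IDR peaks with the highest signal, 20 were mitochondrial and 5 were on X. The highest of all covered 4604 to 4948 in the coding sequence of CYTB, the cytochrome b gene, with a pooled signal of 8355. It had a signal of 3882 in replicate 1 and no overlapping region in replicate 2. The next, at 12270 to 12546 in ND5, a subunit gene of complex I, had 3827 in the pooled list, 2030 in replicate 1 and 2000.2 in replicate 2. The other mitochondrial peaks among the 25 lay nearest the starts of ATP6, ND2, COX1, COX2, ND3, ND4L, ND4, ND5, ND6, the ribosomal RNA gene WBGene00014454 and the tRNA genes WBGene00014473, WBGene00014467, WBGene00014465, WBGene00014461 and WBGene00014455. Of all 21 mitochondrial summits, 19 lay within 500 bp of an annotated start, so these gene names give positions and were not read as targets. Whether the authors' signal allows for the number of mitochondrial genome copies is not known here. The heights therefore cannot be read as stronger binding than at nuclear peaks. Of all 21 mitochondrial peaks, 13 had no region in replicate 2 and 2 had none in replicate 1. Alignments were not analysed, so a peak without a region in the list of a replicate is not shown to lack signal there. Replicate 1 listed 23 mitochondrial regions that covered 6592 of 13794 bp, and replicate 2 listed 7 that covered 1639 bp.

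On the nuclear chromosomes the strongest signals were on X, where 33 of the 37 summits were intergenic. The highest nuclear peak, at X 16682020 to 16682278, was intergenic with a signal of 594 in the pooled list, 311 in replicate 1 and 286 in replicate 2. The others among the 25 were in an intron of Y41G9A.17 (X 2997011 to 2997167, signal 314), in intergenic sequence at X 11094140 to 11094322 (285) and X 9465707 to 9466086 (239.9), and 300 bp from the start of the non-coding RNA gene C18A11.13 (X 8036318 to 8036476, 253). The protein-coding gene with the nearest start to that last summit, 4939 bp away, was xol-1, the switch gene of sex determination, which was picked out after its position was seen. Of the 20 highest nuclear peaks, 16 were on X, 12 of them over 1000 bp from any gene start.

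By number, X carried 37 of the 111 nuclear IDR peaks, or 33.3% (exact 95% interval 24.7 to 42.9%), where its length would give 17.7%. This was a 1.89-fold excess (exact binomial test, 2-sided p = 8.3e-05). Counts on the autosomes were 15 on I, 13 on II, 21 on III, 14 on IV and 11 on V, and the distribution over the 6 chromosomes departed from their lengths (chi-square 26.5, Monte Carlo p = 0.00012 from 100000 draws). The excess on X was 2.77-fold among the 45 nuclear peaks of the 66 with the highest signal.

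**Figure D2:**
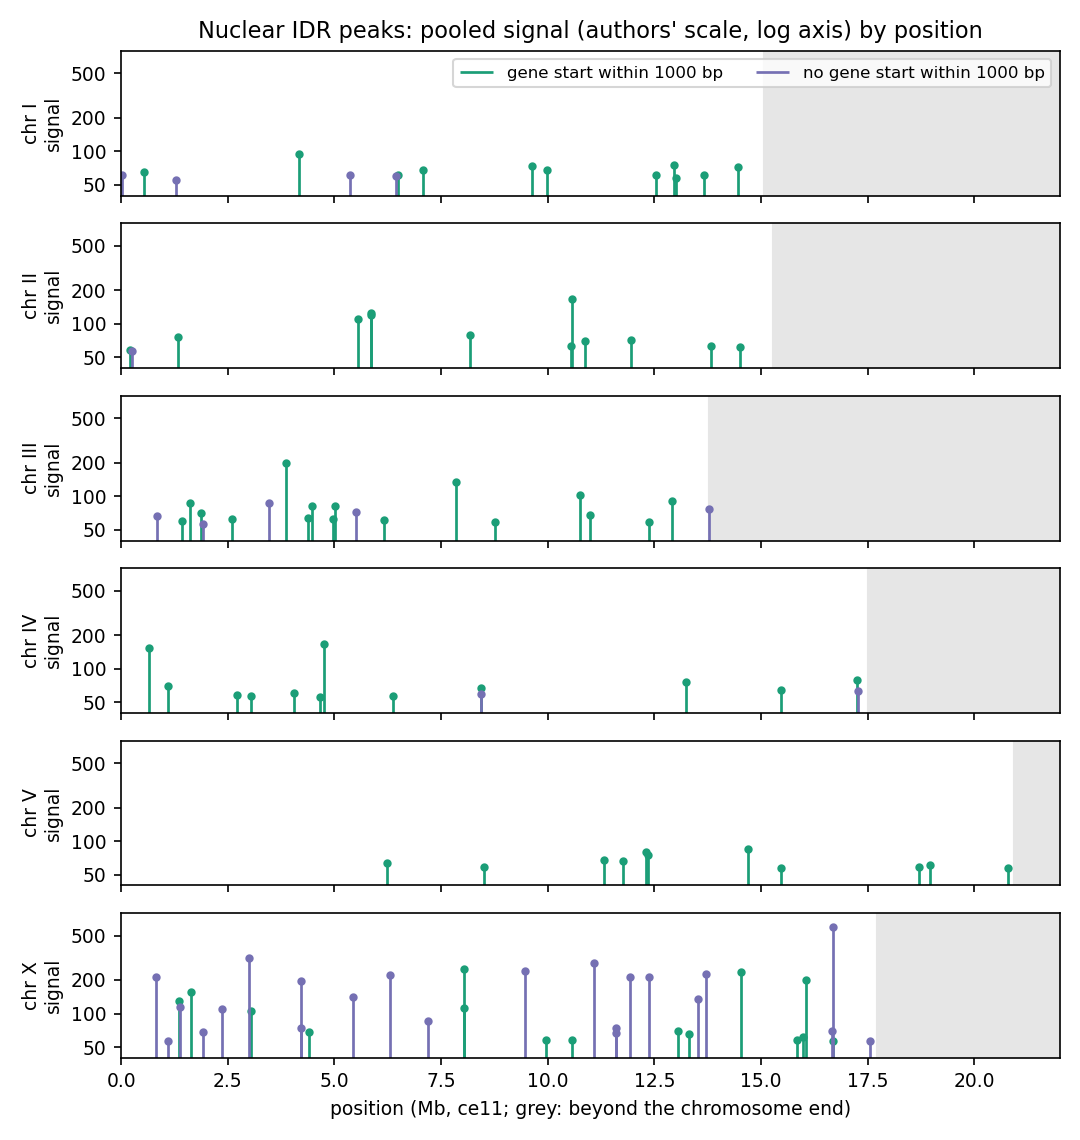
Position on each nuclear chromosome (x axis, Mb in ce11) and pooled signal (y axis, log scale, authors' units) of the 111 nuclear IDR peaks; stems mark positions, and colour shows whether a gene start lay within 1000 bp of the summit. X holds 37 peaks, 22 of them with no gene start within 1000 bp, and the highest at 594.

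The peaks were next placed against gene starts. Of the 132 summits, 85 (64.4%, exact 95% interval 55.6 to 72.5%) lay within 500 bp of an annotated start, against 38.0% ± 3.76 (SD over 10000 random placements on the same chromosomes), a difference of 26.4 percentage points (2-sided empirical p = 0.0002, the smallest these draws can give). Autosomal summits lay at gene starts more often than chance, and X summits did not by this test. On the autosomes 57 of 74 summits (77.0%) were at a start, against 29.6% by chance (n = 74 peaks, empirical p = 0.0002). On X the count was 9 of 37 (24.3%), against 26.4% by chance (n = 37 peaks, empirical p = 0.944), and 22 of the 37 lay over 1000 bp from any start. The 2 shares differed (Fisher's exact test, 2-sided p = 1.33e-07), a test chosen after the values were seen, as were the separate X and autosome values. By annotation 83 of the 111 nuclear summits were intergenic, 11 intronic, 5 in a 5' UTR, 5 in a 3' UTR, 5 in a non-coding exon and 2 in a coding exon.

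Which genes lay at peaks was asked with 20 gene lists, and 5 of them were over-represented among the 101 nuclear genes with a summit within 500 bp of their start. Whether tagged MBF-1 itself gives the signal at these genes was not tested, because no other factor was analysed. Ribosomal protein genes led, with 7 of 81 at a peak where 0.174 would be expected, a 40.1-fold excess (Fisher's exact test, adjusted p = 1.06e-08). The strongest was at rpl-3 (WBGene00004414, chromosome III, 3867854 to 3869587), whose peak lay 284 bp from the start with a pooled signal of 197, 77.8 in replicate 1 and 122 in replicate 2. The peak 311 bp from rpl-20 (chromosome IV, 4749123 to 4749778) had a pooled signal of 166, that 398 bp from rpl-15 (chromosome IV, 653480 to 654576) had 153, and that 451 bp from rpl-35 (chromosome III, 7855134 to 7855646) had 134. The summit near rpl-20 was closer to the start of a neighbour, Y17G9B.5, at 151 bp. The list passed in every alternative run, with 93.9-fold for the 66 peaks of highest signal, 23.2-fold within 200 bp of the start (2 genes, Fisher's exact test, adjusted p = 0.0171) and 21.8-fold among genes with a candidate region at the start. With circular shifts of the summits, which keep neighbouring genes together, all 5 lists passed, at 80.2-fold for ribosomal protein genes, 11.8-fold for tRNA, 35.2-fold for snRNA, 14.0-fold for snoRNA and 31.1-fold for chaperone genes (adjusted p from 0.00133 to 0.0312). Shifted summits also lose the preference of the peaks for gene starts, so fewer genes are expected (0.0873 against 0.174 ribosomal protein genes). These folds therefore mix position at gene starts with list membership and cannot separate the 2.

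Small RNA genes made up 3 of the other lists. Of 612 tRNA genes, 10 were at a peak where 1.32 would be expected (7.59-fold, Fisher's exact test, adjusted p = 8.84e-06). They included WBGene00022939 on X, within 500 bp of both overlapping peaks at C18A11.13 (signals 253 and 112), the neighbours WBGene00023111 and WBGene00023110 on X at a peak with a signal of 106, and WBGene00014296 on X at a peak with a signal of 69.5. The 10 tRNA genes lay at 7 peaks, 2 of them overlapping, because several neighbours shared a peak. Fisher's exact test counts each of these genes separately. Of 129 snRNA genes, 4 were at a peak (14.4-fold, Fisher's exact test, adjusted p = 0.00121). Of these, sls-2.1 (chromosome II, 5844865 to 5844974), sls-2.2 (chromosome II, 5543598 to 5543707) and sls-2.4 (chromosome I, 4172206 to 4172315), which encode the SL2 spliced leader RNA used for downstream genes of operons, had peak signals of 125, 111 and 95.1. The summits at sls-2.2 and sls-2.4 were nearer the starts of C17C3.23 and R12E2.18. The other was R07E5.16, with a signal of 68.2. Of 346 snoRNA genes, 5 were at a peak (6.71-fold, Fisher's exact test, adjusted p = 0.00472), among them the neighbours C51F7.4 and C51F7.3 at a signal of 80.0, W03C9.9 at 71.1 and T03F7.8 at 67.0. Leaving out replicate 2 ended the snoRNA call (3.43-fold, Fisher's exact test, adjusted p = 0.331) and gave 6 snRNA genes (27.6-fold). The 66 peaks of highest signal ended the tRNA call (3 genes, 6.21-fold, Fisher's exact test, adjusted p = 0.0825) and the snoRNA call (2 genes, 7.33-fold, 0.122), at folds near those of all peaks, while 3 snRNA genes gave 29.5-fold. Within 200 bp of the start the folds were 15.3 for tRNA, 21.8 for snRNA and 13.6 for snoRNA genes.

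Of 60 heat shock and chaperone genes, 2 were at a peak (15.5-fold, Fisher's exact test, adjusted p = 0.03). Both encode subunits of the cytosolic chaperonin, cct-1 (chromosome II, 8185443 to 8187601, signal 79.9) and cct-8 (chromosome IV, 1087108 to 1093920, signal 69.8). Both summits were closer to the start of another gene, at 147 bp from mig-5 against 273 bp from cct-1, and at 177 bp from Y55F3AR.2 against 444 bp from cct-8. The call was lost with only protein-coding genes tested (11.3-fold, Fisher's exact test, adjusted p = 0.116) and with the 66 peaks of highest signal (1 gene, 21.1-fold, 0.154), and within 200 bp of the start no gene of the list had a summit. Without replicate 1 the list had 4 genes (25.2-fold), and without replicate 2 it had 3 (29.7-fold). A single gene was at a peak in 3 further lists that did not pass. These were eif-3.C among 37 translation factors (Fisher's exact test, adjusted p = 0.231), cox-5A among 39 respiratory chain genes (0.231) and bli-6 among 195 collagen and cuticle genes (0.86). Without replicate 1 the translation factors passed, with 2 genes (20.4-fold, Fisher's exact test, adjusted p = 0.0145). No gene was at a peak in the remaining 12 lists, which were aminoacyl-tRNA synthetases, histones, amino acid stress response, oxidative stress and detoxification, glycolysis, nuclear hormone receptors, homeobox and neuronal transcription factors, and markers of muscle, intestine, hypodermis, neurons and germline. The number expected in these lists ran from 0.0258 (amino acid stress response) to 0.579 (nuclear hormone receptors). The lack of a gene at a peak is therefore not evidence against signal at these lists.

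**Figure D3:**
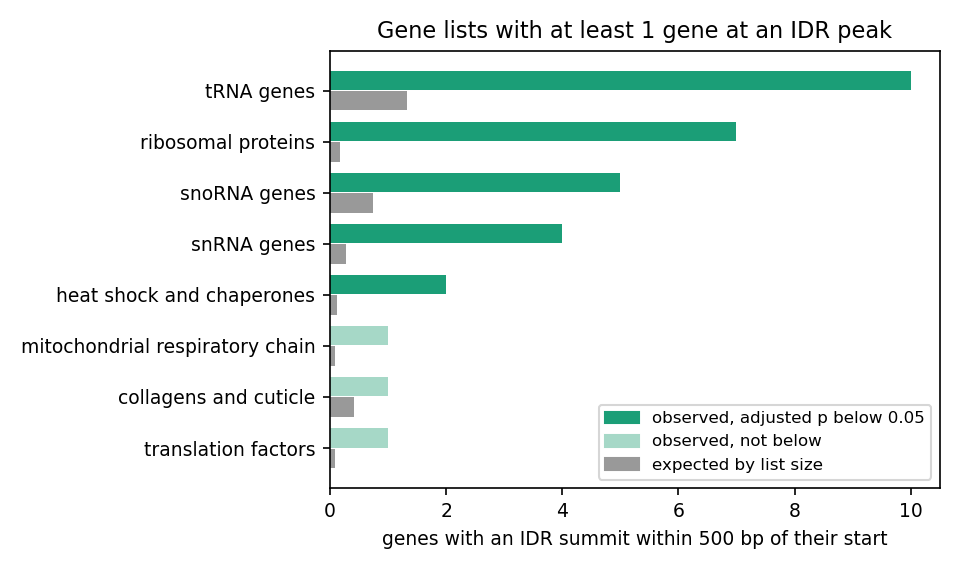
Number of genes per list with an IDR summit within 500 bp of their start (coloured bars, dark where the adjusted p is below 0.05) and the number expected from the size of the list (grey bars), for the 8 lists with any gene at a peak. Ribosomal protein genes stand at 7 against 0.174 expected and tRNA genes at 10 against 1.32.

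Sequence at the summits was compared with pooled candidate regions outside the IDR peaks, matched on location at a gene start but not on G+C. Mean G+C was higher in the IDR peaks (36.3% against 31.7%). Differences in motif frequency can therefore reflect base composition, and this was not tested. Of 13 motifs, 3 were more frequent within 100 bp of the 132 IDR summits. The A box of tRNA promoters (TRGYNNANNNG) was in 41 peaks, 31.1% against 17.6% ± 3.31 (SD over 10000 draws, n = 132 peaks, empirical test, adjusted p = 0.0026). On the nuclear chromosomes it was in 35 of 111 peaks, while 7 nuclear peaks lay within 500 bp of a tRNA gene start. Most nuclear peaks with this sequence were therefore not at an annotated tRNA gene start. The B box (GGTTCGANNCC) was in 6 peaks, 4.55% against 0.810% (n = 132, adjusted p = 0.0091), and the GAGAGA repeat was in 24 peaks, 18.2% against 9.87% (adjusted p = 0.0225). The AP-1 and GCN4 site TGASTCA, the kind of element bound by the yeast partner of MBF1, was in 3 peaks, 2.27% against 1.75% (n = 132, adjusted p = 0.889). The ATF/CRE site and the amino acid response site were in none of the peaks, against 0.787% and 0.196% of the matched regions. GC box, TATA box, E box, SKN-1 site, heat shock element, intestinal GATA site and T block did not pass, with adjusted p from 0.144 to 0.86. No motif passed with the 66 highest peaks, where the A box difference was 12.7 percentage points against 13.4 in all peaks, the B box 2.20 against 3.74 and the GAGA repeat 2.24 against 8.31. None passed with a window of 50 bp either, where the A box was in 14.4% of peaks against 8.79%, the B box in 2.27% against 0.466% and the GAGA repeat in 9.09% against 4.94%. With a window of 200 bp the A box (10.2 points, n = 132, adjusted p = 0.0693) and the GAGA repeat (6.91 points, 0.177) did not pass, the B box did, and the intestinal GATA site was less frequent (25% against 36.6%, adjusted p = 0.0312). Without replicate 2 the A box (5.11 points), the B box (1.51) and the GAGA repeat (3.81) did not pass (n = 132, adjusted p = 0.514 for each), and the GATA site was again less frequent (9.09% against 20.9%, n = 132, adjusted p = 0.0156). Without replicate 1 the A box did not pass (7.39 points, n = 132, adjusted p = 0.113), while the B box and the GAGA repeat did. There the GC box was more frequent (7.58% against 2.95%, adjusted p = 0.0383) and the T block less (18.9% against 30.2%, adjusted p = 0.0217; n = 132). On the autosomes the GAGA repeat passed (12.9 points, n = 74, adjusted p = 0.0286), while the A box (10.6 points, adjusted p = 0.139) and the B box (4.47 points, 0.0715) did not, with fewer peaks.

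**Figure D4:**
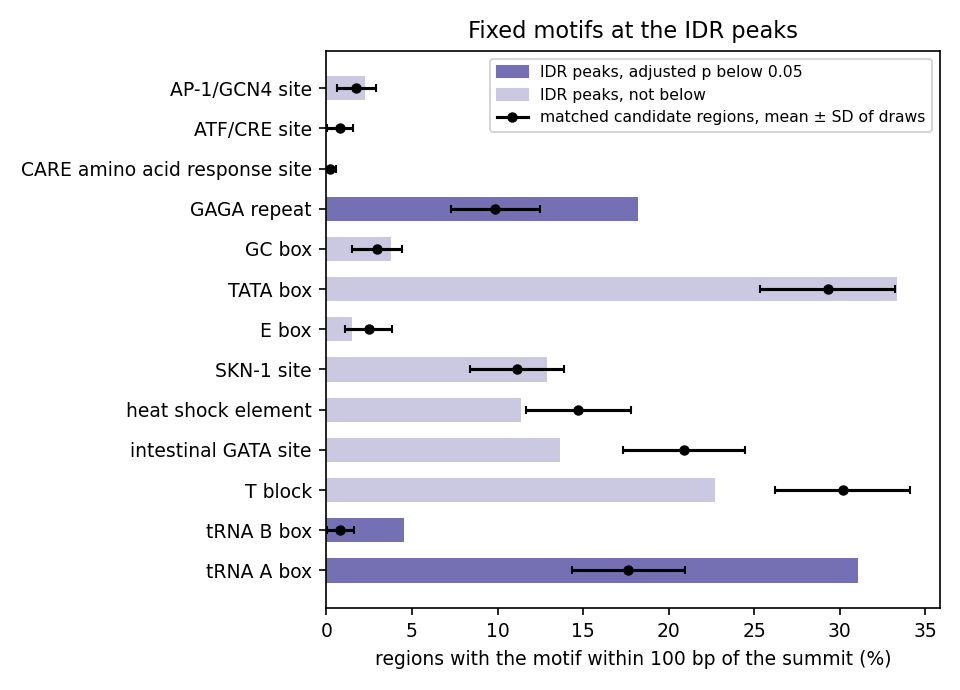
Share of IDR peaks with each of 13 motifs within 100 bp of the summit (bars, in percent, dark where the adjusted p is below 0.05), and the mean and SD of 10000 draws of matched candidate regions (points with error bars). The sequence of the tRNA A box, mostly away from annotated tRNA gene starts, stands at 31.1% against 17.6%, and the GAGA repeat at 18.2% against 9.87%.

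Mean G+C within 100 bp of the summit was 36.3% ± 9.32 (SD over 132 peaks) in the IDR peaks and 31.7% ± 0.554 (SD of the mean over 10000 draws) in the matched regions, a difference of 4.52 percentage points (n = 132, 2-sided empirical p = 0.0002, the smallest these draws can give). The mitochondrial peaks had a median of 22.4%, and without them the difference was 7.29 points. It was 2.23 points in the 132 highest regions of replicate 1 alone and 6.24 in those of replicate 2. With the 66 highest peaks it was 2.22 points, with a window of 200 bp 1.82 and with one of 50 bp 6.80.

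No difference in peak height with location was detected. The 85 peaks at gene starts had a median signal of 75.0 and the other 47 had 74.8 (difference 0.21, 2-sided permutation p = 1). Without the mitochondrial peaks the medians were 68.4 at starts and 73.8 elsewhere (2-sided permutation p = 0.2). On X the 9 peaks at starts had a median of 65.7 and the other 28 had 138 (2-sided permutation p = 0.153). On the autosomes the 57 at starts had 68.6 and the other 17 had 60.2 (permutation p = 0.0576). X and the autosomes thus differed in direction, so the near-equal medians of all peaks do not show equal heights within each.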

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

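The subsets by chromosome, the omission of the 2 peaks farthest from the median and the single counting of overlapping peaks were chosen after the data were seen. Of 69 comparisons of a main result with an alternative, 55 kept the direction, the side of the threshold or a count within 1.5 times. The shared top regions, the excess on X and the G+C difference kept theirs in every alternative run, with shares from 34.8 to 60.6%, a 1.71-fold to 2.77-fold excess and 1.82 to 7.85 points. The rank agreement of the replicates missed the threshold on the autosomes, where rho was 0.209 (the cause was not tested), and in the other alternatives rho ran from 0.482 to 0.891, and to 1 over the 6 mitochondrial peaks with a region in both. Among those 6, the overlapping peaks at ND3 took the same region in each replicate and are not separate points. The gene start excess kept its direction and side of the threshold except on X alone, where it was -2.09 points. The count of gene lists past the threshold was 5, and 2 with the 66 highest peaks and 1 with protein-coding genes, where the small RNA lists have no members; with 1 replicate left out it ran from 4 to 6, with translation factors added without replicate 1. Motifs past the threshold numbered 3, all more frequent in the peaks, and 0 with the 66 highest peaks, 0 with a 50 bp window and 1 on the autosomes; with 1 replicate left out they ran from 1 (less frequent, an intestinal GATA site) to 4 (3 more frequent, and the T block less), and a 200 bp window gave 2 (the B box more frequent and the GATA site less). Fewer peaks enter with the 66 highest and on the autosomes, and beyond that the cause was not tested. The signal difference between peaks at starts and others, 0.21, was -47.9 with the 66 highest, -0.588 within 1000 bp, -5.42 on the nuclear chromosomes, -2.94 with overlapping peaks counted once, -72.3 on X, and from -1.07 to 1.38 with 1 replicate left out, none past the threshold; the cause was not tested. Of 69 comparisons of single lists and motifs, 49 kept their call, 19 lost it in the same direction and 1 fell below the expected count. That was the chaperone list within 200 bp, with 0 genes where 0.064 would be expected, too few to show a change of direction. Replicate agreement and shared regions need both replicates, so neither could be left out. Depth was not known, and with 2 replicates and a peak set selected on pooled signal, weak peaks limit what rank agreement can show.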

Other observations

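The tests chosen only after the result was seen were the share of small RNA peaks at coding starts, the share of genes in gaps as long as that around mbf-1, the share of regions of matched G+C on X, the shares with overlapping peaks counted once, and each comparison with a second set of peaks or candidate regions below other than the recruitment motif in other X regions. The patterns themselves were noticed in the data, so each account is a hypothesis, and with 1 group no biological explanation from the design was tested.

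The nuclear genes at peaks were a mixture of kinds. Of the 101 genes with a summit within 500 bp of their start, 59 were protein-coding (58.4%, against 42.6% of all nuclear genes), 21 were other non-coding RNA genes (20.8% against 16.6%), 10 were tRNA genes (9.9% against 1.31%), 5 were snoRNA genes, 4 were snRNA genes, 1 was a pseudogene (0.99% against 4.54%) and 1 was a piRNA gene (0.99% against 32.8%). Of the 66 nuclear summits at a start, 53 lay upstream of the nearest start and 13 downstream. Chosen after their values were seen, peaks lay at cdc-48.1, an AAA ATPase gene of protein degradation (172 bp from the start, signal 166), and at tba-2, an alpha-tubulin gene (signal 75.0).

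The 22 X peaks over 1000 bp from any gene start had a median signal of 138, against 69.5 for the other X peaks, a difference that was not tested. A candidate explanation of these peaks is binding at recruitment sites of the dosage compensation complex, which carry a motif around TCGCGCAGGG. The motif with at most 1 mismatch was within 190 bp of 11 of the 22 summits (50%, exact 95% interval 28.2 to 71.8%), against 6 of 5810 other X candidate regions (0.103%; Fisher's exact test, p = 1.31e-24), 6 of the 15 nearer X peaks and 1 of 74 autosomal IDR peaks. A share above 50% had been set as the bound, and 2 of the 22 peaks overlap; with overlapping peaks counted once the share was 11 of 21 (52.4%, exact 95% interval 29.8 to 74.3%), so the motif is over-represented but which side of the bound its share takes depends on the counting, and the account of the set as a whole stays open. G+C content as the whole cause of their number on X was argued against, since candidate regions drawn to match the 34 nuclear peaks over 1000 bp from a start in G+C, and themselves over 1000 bp from any start, lay on X in 18.7% (middle 95% of 10000 draws 5.88 to 32.4%), against 22 of the 34 peaks (64.7%, exact 95% interval 46.5 to 80.3%), as were several genomic copies, since 4.55% (1 of 22) had a second match of 100 bp at 90% identity. Whether tagged MBF-1 or a general feature of open chromatin gives this signal was not tested, because no other factor was analysed here. The same holds for the other peaks.

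The 16 nuclear peaks within 500 bp of a tRNA, snRNA or snoRNA gene start raise the question of repeated sequence. Of these, 8 (50%, exact 95% interval 24.7 to 75.3%) had a second genomic match, which meets the bound set for several genomic copies. The same was true of 128 of 488 other candidate regions at such starts (26.2%; Fisher's exact test, p = 0.0453), and with overlapping peaks counted once of 7 of 14 peaks (50%) against 115 of 434 (26.5%), a difference that missed the threshold (Fisher's exact test, p = 0.0666). A match here had to span at least 100 bp at 90% identity. Copies limited to a shorter gene, such as a tRNA gene alone, were therefore not counted. A match at 90% identity also need not share reads. The shares therefore cannot show whether reads shared between copies add to these peaks, and this was not tested. The authors' treatment of such reads is not given in the sources used here. A protein-coding start in the same window was found for 6.25% (1 of 16, interval 0.158 to 30.2%), too few peaks to meet the bound of under 25% set for its upper limit.

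The gap around mbf-1 held 24 whole genes, 12 of them protein-coding. Chance spacing was argued against, since pooled gaps as long held 0.661% of protein-coding genes, and so were repeated sequences, since 4.36% of the gap's bases lay in a second genomic match. What stays open, untested, is that the authors' processing removed the region or that extra copies of it in the transgene raised the control; the extent of the transgene is not given in the sources used here.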
